A study of Homo sapiens with 8 samples.

How the data were processed

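Human bronchial smooth muscle cells, the contractile cells of the airway wall, were infected with an adenovirus that carried HSP27, a small heat shock protein, either in the wild type form (HSP27-WT) or in a phosphorylation-mutant form (HSP27-3A). Infection lasted 4 days at a multiplicity of infection of 40, and the cells were stimulated for 20 h with IL-1beta, TNF-alpha and interferon-gamma at 10 ng/mL, per the labels. Total RNA was measured on 8 microarrays with 2 channels each. The array titles name 3 experiments and end in wt3 (4 arrays), 3a3 (3 arrays) or wt5 (1 array). The endings were read as likely naming the construct in the Cy3 or Cy5 channel, so that the wt3 arrays form 1 dye orientation and the 3a3 and wt5 arrays form the other. The dyes of each RNA, the direction of the ratio and whether ratios had already been turned to 1 direction were not given in the sources used here.

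The deposited table holds 1 value per probe and array, used as a log2 ratio of the 2 channels. The deposited values run above and below 0, and the base of the logarithm is not given in the sources used here; base 2 was assumed, and every log2 value below rests on that. How the authors corrected background and normalized the deposited ratios is likewise not given. Array medians from -2.04 to 1.04 show that the deposited ratios were not centred on a median of 0. Channel intensities were not used here, so signal over background was not known, and the number of arrays limits the precision. The table had 1081 probes with 0 missing values. In the platform annotation 965 probes had 1 gene symbol, 8 had several and 108 had none. Probes of 1 gene were averaged, and probes with several symbols or none kept their probe identifier, which gave 1072 features (called genes below), 956 of them named. Only 7 genes had more than 1 probe. The symbols were compared through Entrez identifiers with a RefSeq gene table and matched there, except for CCR2, whose identifier was not found.

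Because the labels leave the direction open, 2 quantities were tested for every gene in each experiment. The reversing part was the mean of the wt3 arrays minus the mean of the other orientation, divided by 2. The shared part was the sum of these means divided by 2. If the ratios are Cy5 over Cy3 and wt3 means wild type RNA in Cy3, a positive reversing part is a higher level with HSP27-3A. If the ratios had been turned to 1 direction before deposit, the shared part holds the construct difference and the reversing part a dye difference. No direction is therefore given as fact. The replicate was the experiment (n = 3), because the 4 arrays of experiment 2 may share RNA. Where they were paired, arrays with the same number in their titles formed a pair; the labels do not say that the numbers mark pairs. Nothing in the labels says that the experiments used separate donors or cultures. Over the 3 experiments the limma p-values of single genes therefore measure only the spread between these experiments, pooled wholly or partly over genes. That spread may be technical.

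The test was limma (version 3.58.1, in R 4.3.3), with lmFit and eBayes on the 3 values per gene against 0 and a Benjamini-Hochberg adjusted p below 0.05. As deposited, it gave every gene the same standard error, 0.42 in the reversing and 0.57 in the shared part. A gene's own SD over the experiments therefore did not enter its p-value there. The test, the values as deposited, 20 gene lists, the named genes and 15 other fits were chosen before the data were examined. Centring each array on its median was 1 of those other fits. The array offsets made the error of the deposited values large, so the centred values stand beside the deposited ones in the text; the choice to show both came after the offsets were seen. A further 12 fits were added after seeing the data. Gene lists with at least 5 measured members (13 of 20) were tested with camera, which asks whether a list moves relative to the other genes, at a preset correlation of 0.01, adjusted over 26 tests. At that setting its p-values compare genes with genes, so a small one does not mean that the experiments agreed. Camera with an estimated correlation was run as well, and so was fry, which tests a list against no change. With 3 values per gene the estimated form has few degrees of freedom, so hardly any list could pass after adjustment. A call lost there is left undecided by it. Array correlations are Pearson's r across probes, which are not independent replicates.

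The named genes were those past the threshold with the same sign in all 3 experiments. Where fewer than 5 passed in a direction, they were the 5 of smallest unadjusted p that had the same sign throughout. Added to these were preset inflammation and reference genes, of which HSPB1, IL6, CXCL8, CCL5 and VCAM1 were measured, and the 3 members of smallest p from each tested list. The rule was applied to the deposited and to the centred values. A member of the actin cytoskeleton list that the rule names is not reported here, so the members it stands with in the reversing part are left out of the account of that list too. Genes of experiment 2 alone were named after their values were seen. Smooth muscle contractile genes had 0 measured members, and lists under 5 members were not tested.

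The fits were tested on simulated data with 200 changed genes among 1072. For the reversing part as deposited, 0% of genes with a change of 0.5, 16.4% with 1 and 100% with 2 (log2) were recovered. After centring the shares were 25.4%, 89.6% and 100%. For the shared part they were 0%, 5.97% and 62.1% as deposited, and 28.4%, 91.0% and 100% after centring. The simulated noise was independent and had 1 spread per array for every gene. In the real centred data errors differed between genes, with a moderated standard error of 0.16 for FGF5 and 0.43 for CCL5 (reversing part). The shares after centring may therefore be too high for these data, and an absence of calls does not exclude changes of 1.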

Results

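The series compared bronchial smooth muscle cells that received phosphorylation-mutant HSP27-3A with cells that received HSP27-WT, all under a mix of inflammatory cytokines. Each of 8 arrays carried both RNAs, and the arrays fell into 3 experiments. Experiment 1 had 1 wt3 and 1 wt5 array, experiment 2 had 2 wt3 and 2 3a3 arrays, and experiment 3 had 1 wt3 and 1 3a3 array. There were no unstimulated or uninfected cells among the arrays used here, so every value is a ratio between the constructs or between the dyes.

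HSPB1, the gene of HSP27 itself, gave the highest shared log ratio of all 1072 genes in experiment 2, 1.67 after centring, against 0.69 for the gene next in rank, TNFRSF1B. The pairs of that experiment, as numbered in the titles, gave 0.98 and 2.36. In experiments 1 and 3 the shared value of HSPB1 was -0.74 and -0.13, so that over the 3 experiments it was 0.27 ± 1.25 (SD, n = 3). Its reversing value was 0.14 ± 0.51 (SD, n = 3), with -0.03, 0.72 and -0.26 in experiments 1, 2 and 3. Neither passed the limma test over the 3 experiments after centring (unadjusted p = 0.499 and 0.573). In fits of experiment 2 alone, chosen after the data were seen, the calls depended on how its arrays were paired. The reversing value of 0.72 passed with the pairs as numbered in the titles, 0.69 and 0.75 (limma adjusted p = 0.000192), but not with the pairs crossed, 0.03 and 1.41 (adjusted p = 0.273), or without pairing (adjusted p = 0.139). The shared value passed with crossed pairs, 1.64 and 1.70 (adjusted p = 3.38e-22), and without pairing (adjusted p = 0.0138), but not with numbered pairs (adjusted p = 0.321). With numbered pairs in the reversing part and crossed pairs in the shared part, the fit gave every gene the same error. The closeness of 0.69 and 0.75, or of 1.64 and 1.70, therefore did not enter those calls. Both viruses carry HSP27, so the probe does not tell the constructs apart and checks no label.

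The arrays differed in level and spread. The median log ratio was 0.37 on the wt3 and -0.26 on the wt5 array of experiment 1. In experiment 2 it was -1.37 and 0.01 on the wt3 arrays and 1.04 and 0.11 on the 3a3 arrays. In experiment 3 it was -1.02 on the wt3 and -2.04 on the 3a3 array. The SD across probes was 0.336 to 0.636 in experiments 1 and 2, and 0.911 and 0.854 on the arrays of experiment 3. All 6 pairs of arrays from the same experiment with opposite orientation correlated negatively across probes, with a mean r of -0.244 and a range of -0.389 to -0.0906. The 2 pairs of the same experiment and orientation had r of 0.375 and 0.391. Between experiments the mean r was 0.0136 for the 10 pairs of the same orientation and -0.0256 for the 10 pairs of opposite orientation.

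**Figure D1:**
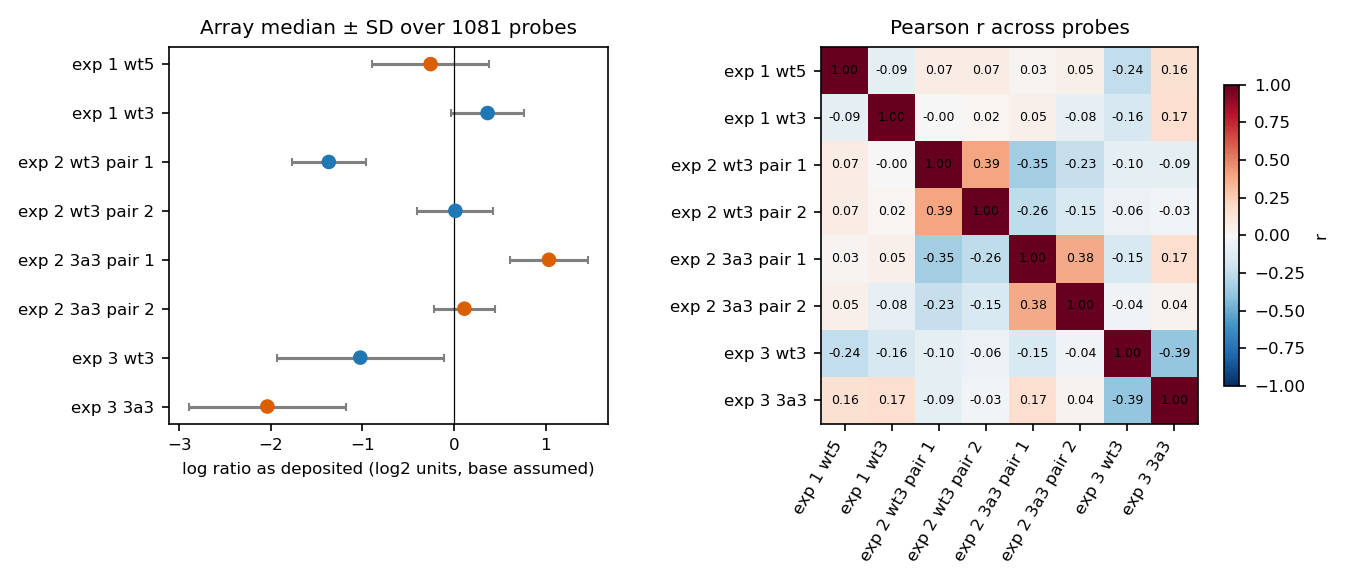
Left, median log ratio as deposited of each of the 8 arrays (point) with the SD across 1081 probes (bar), in log2 units with the base assumed; blue marks wt3 arrays and orange the 3a3 and wt5 arrays. Right, Pearson's r across probes for each pair of arrays, where arrays of opposite orientation in the same experiment have r from -0.389 to -0.0906.

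The part that reversed with orientation answers whether the 2 RNAs differed, if the ratios are dye over dye. The largest positive values among genes with 1 sign in all experiments belonged to MAP3K8, a kinase upstream of ERK signalling in inflammation, GNA13, a G protein alpha subunit, and CDKN1A, the cyclin-dependent kinase inhibitor p21. As deposited these were 0.88 ± 0.62, 0.76 ± 0.59 and 0.73 ± 0.96 (SD, n = 3). SLC1A1, a glutamate transporter, was at 0.64 ± 0.38 and the kinase MOS at 0.62 ± 0.53. The most negative were AIMP1 at -0.86 ± 0.57, and the growth factors PDGFB at -0.82 ± 0.68, TGFB2 at -0.79 ± 0.90, FGF7 at -0.77 ± 0.44 and VEGFC at -0.76 ± 0.46. In limma 0 of 1072 genes passed, the smallest adjusted p was 0.999, and 6 genes had an unadjusted p below 0.05 where 53.6 are expected by chance.

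With each array centred on its median the moderated standard error fell from 0.42, the same for every gene, to 0.19 for the median gene. Again 0 genes passed (smallest adjusted p = 0.668), with 36 genes at an unadjusted p below 0.05, 18 in each direction. MAP3K8 was then at 0.82 ± 0.27, GNA13 at 0.69 ± 0.28 and MOS at 0.56 ± 0.08 (SD, n = 3). TCEA1, a transcription elongation factor, was at 0.64 ± 0.15 and KLHDC10 at 0.54 ± 0.09. On the negative side HIF1A, the oxygen-regulated transcription factor subunit, was at -0.70 ± 0.45, the signalling adaptor SH3BP2 at -0.62 ± 0.35, the proteasome subunit PSMA4 at -0.59 ± 0.22, HTT at -0.54 ± 0.24 and the growth factor FGF5 at -0.48 ± 0.06. Of the 1072 genes, 375 (35.0%) had the same sign in all 3 experiments after centring and 68 (6.34%) as deposited, where chance gives about 25%; as deposited the medians of the experiments lay at 0.30, -0.62 and 0.51. The correlation of the reversing part between experiments was -0.0240, 0.0969 and 0.0682 across genes.

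Of the preset inflammation genes CXCL8, IL6, CCL5 and VCAM1 were measured, and none passed in limma over the 3 experiments, deposited or centred (smallest unadjusted p = 0.0858, for CXCL8 after centring). The reversing value after centring was -0.36 ± 0.19 for CXCL8, the neutrophil chemokine interleukin-8, with -0.24, -0.25 and -0.58 in experiments 1 to 3. It was 0.14 ± 0.45 for IL6, -0.57 ± 1.11 for the chemokine CCL5 and -0.55 ± 1.00 for the adhesion molecule VCAM1 (SD, n = 3). CCL5 and VCAM1 stood at -1.85 and -1.70 in experiment 3 and between -0.07 and 0.17 in the other experiments.

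Growth factors and their receptors lay below the other genes in the reversing part, with 17 of 18 measured members negative and a list median of -0.25 against 0.05 for all genes (camera adjusted p = 8.88e-05 at the preset correlation, but adjusted p = 0.955 with an estimated correlation). After centring 18 of 18 were negative, 8 of them in all 3 experiments (camera adjusted p = 0.000324, and adjusted p = 0.811 with an estimated correlation). No member passed by itself, over all genes or adjusted over the list alone. VEGFC was at -0.82 ± 0.71, FGF7 at -0.83 ± 0.84 and HGF, the hepatocyte growth factor, at -0.57 ± 0.53 after centring. Cytokines and chemokines lay lower as a list too, with 14 of 17 negative and a median of -0.27 (adjusted p = 0.00403, but adjusted p = 0.955 with an estimated correlation; centred, adjusted p = 0.00994 and 0.811). Among these IL1A was at -0.56 ± 0.49 and IL1RN, the interleukin-1 receptor antagonist, at -0.57 ± 0.68 after centring. Fry, which asks whether a list moves 1 way and does not compare it with other genes, gave an adjusted p of 0.834 for each of these lists. The growth factor list median relative to all genes was -0.18, -0.07 and -0.88 in experiments 1, 2 and 3. Without experiment 3 it was -0.12 and the call ended (adjusted p = 0.110). With arrays scaled to a common spread the growth factor call stayed (camera adjusted p = 0.00147, but 0.995 with an estimated correlation). The cytokine list was at -0.22, 0.05 and -0.59 after centring, so that it turned in experiment 2. Its call was lost with arrays scaled to a common spread (adjusted p = 0.114), with the running median along the probe numbers removed (adjusted p = 0.121) and without experiment 3, where it was at -0.13 (adjusted p = 0.466). With the wt5 array turned like the wt3 arrays neither list passed as deposited (adjusted p = 0.0770 and 0.384). After centring the growth factor list then passed (camera adjusted p = 0.0485, but 0.874 with an estimated correlation) and the cytokine list did not (adjusted p = 0.662).

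The other 11 lists did not pass in the reversing part, for which counts of signs and p-values are of the deposited values unless named as centred. Heat shock proteins and chaperones had 6 of 7 members positive, deposited (adjusted p = 0.170) and centred (adjusted p = 0.119), with DNAJB1, a co-chaperone of HSP70, at 0.55 ± 0.30, HSPA1A, an inducible HSP70, at 0.36 ± 0.14 and the mitochondrial chaperonin HSPD1 at 0.33 ± 0.12 after centring. Oxidative stress and glutathione genes had 9 of 10 positive, deposited (adjusted p = 0.170) and centred (adjusted p = 0.0950), among them the superoxide dismutase SOD1 at 0.39 ± 0.17, the quinone reductase NQO1 at 0.37 ± 0.21 and the peroxiredoxin PRDX2 at 0.31 ± 0.10 after centring. Cell cycle genes had 20 of 25 positive (adjusted p = 0.126; 16 centred) and MAP kinase pathway genes 12 of 16 (adjusted p = 0.368; 10 centred). Actin cytoskeleton and adhesion genes had 9 of 16 negative (adjusted p = 0.183; 10 centred). Extracellular matrix genes had 18 of 28 positive, apoptosis genes 12 of 20, interferon response genes 11 of 15 and NF-kB targets 11 of 18 (adjusted p = 0.837 for each of these 4). After centring the majority was gone or turned, with 14 of 28, 7 of 20, 7 of 15 and 8 of 18 positive in the same order. Endothelial markers had 4 of 6 positive (adjusted p = 0.628) and epithelial markers 4 of 6 (adjusted p = 0.507).

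**Figure D2:**
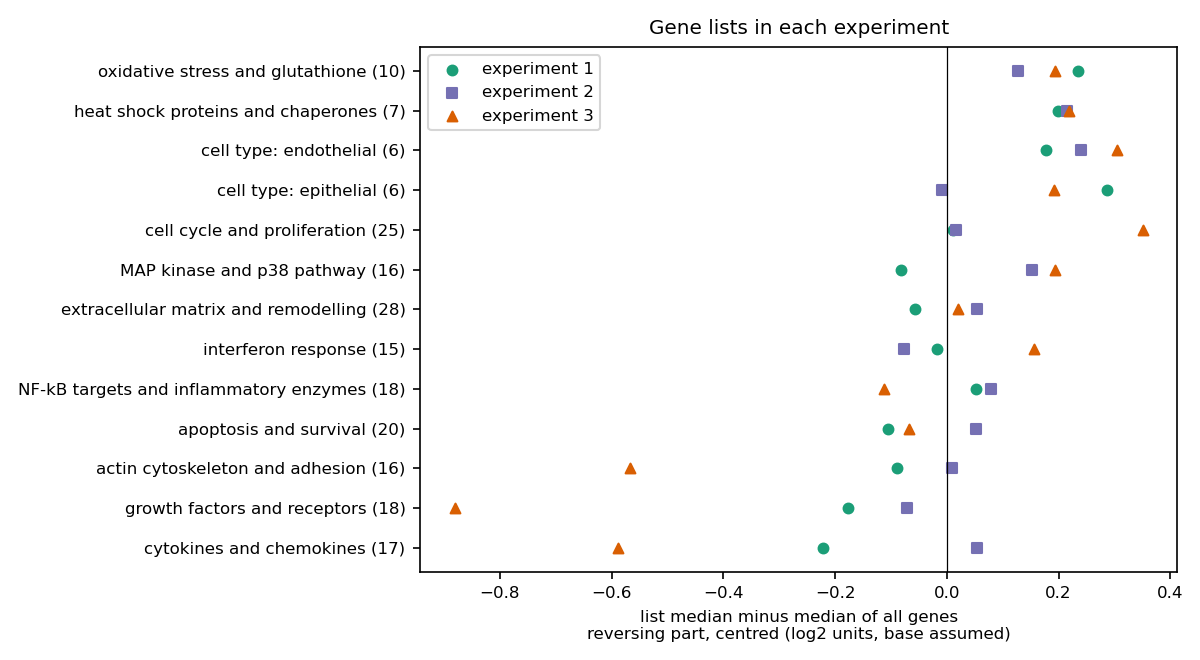
Median of each tested gene list minus the median of all genes, reversing part after centring, in log2 units with the base assumed; each symbol is 1 experiment and the number of measured members is in brackets. Growth factors and receptors lie at -0.18, -0.07 and -0.88 in experiments 1, 2 and 3.

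Experiment 2, the only experiment with 2 arrays of each orientation, was fitted alone after the data were seen. Its arrays were paired by the numbers in their titles, which the labels do not explain; arrays with the same number had r of -0.348 and -0.149 and those with different numbers -0.257 and -0.232. In its reversing part, JAK3, a kinase of cytokine receptor signalling, was at 1.65 and 1.61 in the pairs. VEZF1, a zinc finger transcription factor, was at 1.47 and 1.77, and SFN, the 14-3-3 sigma protein, at 1.72 and 1.41. NRGN was at 1.58 and 1.15, ACKR1, an atypical chemokine receptor, at 1.26 and 1.33, LYL1 at 1.16 and 1.35, and PGF, the placental growth factor, at 1.43 and 1.00. IL6 was at 0.64 and 0.41 (adjusted p = 0.0164; adjusted p = 0.0763 with crossed pairs and 0.0499 without pairing), while it stood at -0.36 in experiment 1 and 0.25 in experiment 3. With limma 78 genes passed, 66 positive and 12 negative. In this fit every gene had the same standard error, 0.157, so a gene's agreement between the pairs did not enter its call. With the pairs crossed 40 of these 78 passed, 39 positive and 1 negative, and no others. Without pairing of the 4 arrays 42 of the 78 passed, 41 positive and 1 negative. The calls common to all 3 fits were 38, the 7 genes from JAK3 to PGF among them. The reversing values of the pairs correlated across genes with r = 0.505 as numbered and 0.515 crossed. In experiment 1 JAK3, VEZF1 and SFN stood at -0.43, -0.19 and -0.35, and in experiment 3 at 0.48, -0.59 and -1.07. Of the 78 genes, 34 had the same sign in experiment 1 and 35 in experiment 3. The pairs come from 1 experiment and may share RNA, so these p-values cover only the spread between its arrays.

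**Figure D3:**
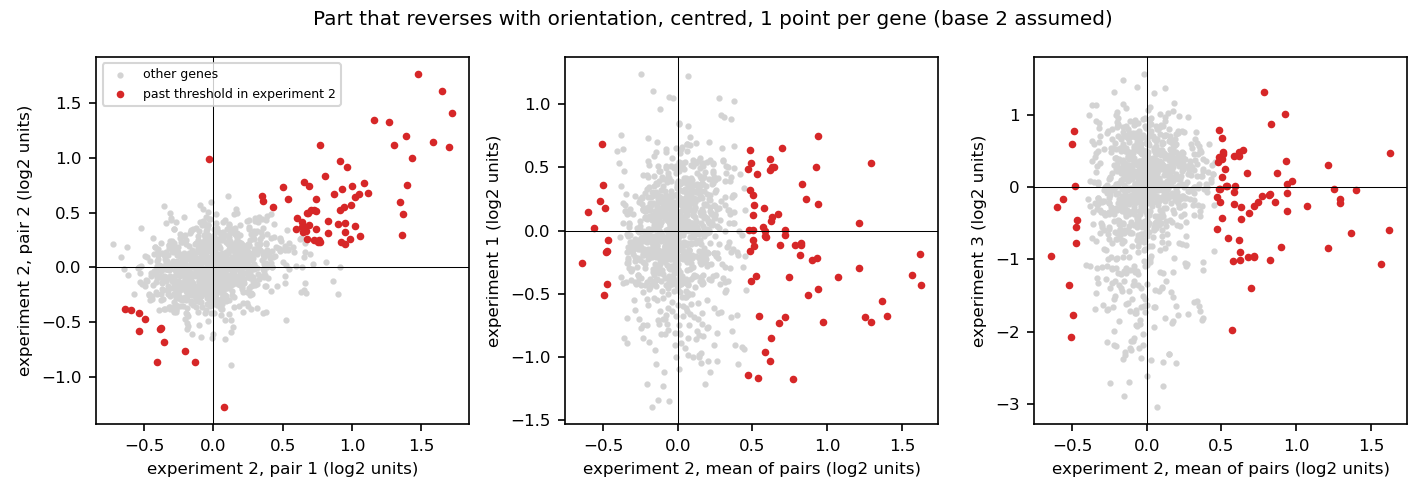
Reversing part per gene after centring, in log2 units with the base assumed, for pair 1 against pair 2 of experiment 2, paired as numbered in the titles (left), and for the mean of these pairs against experiment 1 (middle) and experiment 3 (right). Red points are the 78 genes past the threshold in experiment 2, 66 of them positive; 34 keep their sign in experiment 1 and 35 in experiment 3.

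The part shared by both orientations answers whether the RNAs differed if the ratios had been turned to 1 direction before deposit. As deposited its median over all genes was -0.53, which follows the low arrays of experiment 3 (median -1.64 there, against 0.06 and -0.05), so genes are given relative to it through centring. Among the genes of smallest p PSMA4 was at 0.91 ± 0.76, CTSC, a lysosomal protease, at 0.70 ± 0.62, the cytokine IL4 at 0.65 ± 0.56, ITIH2 at 0.57 ± 0.30 and the integrin subunit ITGA5 at 0.50 ± 0.22 (SD, n = 3). On the negative side were the laminin subunit LAMB2 at -0.59 ± 0.70, the phospholipase PLCG2 at -0.48 ± 0.37, the monoamine transporter SLC18A2 at -0.47 ± 0.46, the glutathione transferase GSTM1 at -0.45 ± 0.35 and the catenin CTNNA1 at -0.42 ± 0.17. A shared value is a mean and can rest on 1 orientation or 1 array. IL4 was at -0.32 to 0.05 on the wt3 arrays, but 2.08 on wt5 and 1.81 on the 3a3 array of experiment 3. CTSC was at 2.72 on wt5 and -0.18 to 0.75 elsewhere. PLCG2 was at -2.43 on the 3a3 array of pair 2 in experiment 2 and -0.59 to 0.12 elsewhere. In experiment 3 SLC18A2 had opposite signs, -3.69 on wt3 and 1.70 on 3a3. In limma 0 of 1072 genes passed as deposited (smallest adjusted p = 0.649, 0 genes at an unadjusted p below 0.05) and 0 passed after centring (smallest adjusted p = 0.990, 29 genes, 24 positive and 5 negative). The same sign in all 3 experiments was seen for 255 genes (23.8%) after centring and 299 (27.9%) as deposited.

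As deposited the shared values were largely negative. LAMB2 was at -1.10 ± 1.58, SMAD4, the common mediator of TGF-beta signalling, at -0.99 ± 1.47, PLCG2 at -0.99 ± 0.76, SLC18A2 at -0.98 ± 1.34 and the unnamed probe OH8090 at -0.97 ± 1.40; PSMA4 at 0.40 ± 0.51 was the only gene named on the positive side. None of the 13 lists passed in the shared part. As deposited every measured member was negative in 11 of the 13 lists, with the median of all genes at -0.53. The smallest adjusted p, 0.183, belonged to the endothelial markers, and that of the epithelial markers was 0.203. After centring 5 of 6 endothelial and 6 of 6 epithelial markers were negative (adjusted p = 0.234 and 0.205). CXCL8 was at -0.18 ± 0.64, IL6 at 0.21 ± 0.18, CCL5 at 0.26 ± 0.58 and VCAM1 at -0.18 ± 0.81 after centring.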

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

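The leave-out of experiment 3, the comparison of list sizes between experiments, the tests on experiment 2 and the splits of the 8 arrays were chosen only after the results were seen, and the running median and the estimated correlation outside the reported fit were settings added after seeing the data.

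On the 4 wt3 arrays, 15 of 78 items had 1 array far from the others. About 1 in 20, or 3.9, would be expected by chance for independent items on arrays of equal spread. These arrays differed in spread, so 3.9 is not their chance rate. The named genes were picked partly for large values, which adds to the count of 15. In 13 of the 15 items the distant array was that of experiment 3. Its SD across probes was 0.911, against 0.397 to 0.414 on the other wt3 arrays. After centring, that array gave -3.69 for SLC18A2, -3.11 for FGF7, -2.82 for VCAM1, -2.78 for LIF, -2.58 for CTNNB1, -2.45 for SOCS3 and -2.24 for CSF3. It gave -1.78 for FAS, -1.62 for TNFRSF1A, -1.41 for ILK, -0.65 for TGFB2 and 0.55 for GADD45A. The other distant values were 1.41 for MAP3K8 on the wt3 array of pair 1 and 1.86 for SLC1A1 on that of pair 2, both in experiment 2.

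The growth factor list lay below the other genes by -0.30 in the reversing part, a call of camera at its preset correlation that is lost with an estimated one (adjusted p = 0.811 after centring). With 3 experiments the estimated form has few degrees of freedom, so that loss does not decide the matter. A trend along the probe numbers is argued against as the whole cause, since the shift was -0.27 after each array's running median was removed (adjusted p = 0.00819 at the preset correlation, 0.744 with an estimated one). Experiment 3 carried most of it, since the shift without experiment 3 was -0.12 and its call ended (adjusted p = 0.0737 after centring). A construct effect of similar size in the 3 experiments stays open, an explanation that was reworded after its value was seen. The smallest shift of an experiment was 0.0810 of the largest (95% bootstrap interval over genes -0.0605 to 0.149), but the SD across genes was 0.730 in experiment 3 against 0.389 and 0.270 in experiments 1 and 2. In units of that SD the ratio was 0.219 (-0.123 to 0.378), too wide an interval to decide. Whether experiment 3 differed in its cells or in its arrays stays open too, as does a construct effect that varied between experiments.

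Experiment 2 gave 78 genes in the reversing part where the 3 experiments together gave 0. Noise of single arrays is argued against, because the pairs, made of different arrays, correlated with r = 0.505 as numbered in the titles and 0.515 when crossed. The number of genes depends on the fit, since 40 of the 78 passed with the pairs crossed. With numbered pairs every gene had the same standard error, 0.157, so these calls rank genes by their mean alone. With crossed pairs the error differed between genes, so the counts differ in the error used as well as in the pairing. Slopes of these 78 genes in the other experiments gave no sign of a construct effect common to the 3 experiments. The larger was -0.100 in experiment 3 (95% bootstrap interval over genes -0.271 to 0.0792). They gave no sign either of a dye effect of the probes that recurs on every swapped pair, the smaller being -0.167 in experiment 1 (-0.277 to -0.0472). For the 40 genes called with both pairings the slopes were -0.165 (-0.292 to -0.0273) and -0.162 (-0.343 to 0.0261) in experiments 1 and 3. Experiments 1 and 3 had 1 pair of arrays each, so intervals over genes leave out the spread between arrays. The slope in experiment 1 also rests on the reading of the wt5 array. Neither explanation is therefore excluded. A construct difference present in experiment 2 alone and a labelling effect of that experiment were not tested and stay open.

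Chance was examined through other assignments of the arrays. Of the 12 assignments of orientation within the experiments, 9 gave as many lists as the real one (2 in the real one, highest other 3, adjusted over the reversing part alone). All 12 gave as many genes (highest other 0), which decides nothing, since the real one gave 0 and no assignment can give fewer. With 12 assignments no share under 0.05 can be had. In the centred fit of the 8 arrays, 1 of 35 splits, the real one, reached its 96 genes at an unadjusted p below 0.05, and the highest other gave 90. These splits ignore that arrays are grouped in experiments. Among the 12 that keep both orientations in each experiment the highest other gave 79, but 12 are too few for a share under 0.05. In the fit of the 3 experiments the real assignment gave 36 such genes centred (highest other 37) and 6 as deposited (highest other 421). As deposited 3 assignments gave 174, 389 and 421, those in which the medians of the 3 experiments had 1 sign, so these counts follow the offsets of the arrays. No gene passed after adjustment in these fits with the real assignment.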

How the results depend on the processing

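The 15 planned fits called 0 genes in either part, as did 9 of the 12 fits added after seeing the data; the exceptions were those of experiment 2 alone, with 78 genes in the reversing part, 40 there and 7 in the shared part with its pairs crossed, and 42 and 1 without pairing. The filters on missing values removed no probe. Of the values of genes named from the deposited data, 11 of 690 planned ones in the reversing part and 21 of 720 in the shared part changed direction. Among added ones these were 39 of 552 and 92 of 576. Values past the threshold, 21 and 3 among the added ones, were not checked for direction. HSPB1 was among them, with a shared value of -0.24 as deposited and 1.67 in experiment 2 alone. Some planned fits, such as those filters, could not change a value, so the low planned counts say little on robustness. The experiment as a replicate block gave 2 lists and 0 genes, as did the 4 pairs as replicates; centred, these fits, the 4 pairs crossed and the 8 arrays without a block each gave 3 lists, oxidative stress being added (adjusted p = 0.0395 to 0.0494, 0.703 to 0.830 with an estimated correlation). The count of lists past the threshold, 2 in the reported fit, fell to 1 with arrays scaled to a common spread, 0 with the wt5 array turned (1 when also centred), 1 with the running median removed, 0 in experiment 2 alone (with crossed pairs 1, heat shock proteins in the shared part, adjusted p = 0.00709, or 0.949 with an estimated correlation), 0 with an estimated correlation and 0 with fry, which asks another question, a list against no change. The heat shock list called in experiment 2 holds HSPB1, whose shared value there was 1.67 against a list median of 0.15. It was not tested without HSPB1. Leaving out an experiment gave 1 to 2 lists. Without experiment 3 these were other calls, growth factors and cytokines both higher in the shared part (adjusted p = 0.0292 and 0.0266, but adjusted p = 0.951 for each with an estimated correlation). The growth factor median relative to all genes was -0.20 with wt5 turned and -0.0714 in experiment 2 alone (paired or not), and -0.49 to -0.12 when an experiment was left out. The cytokine median was -0.19 with scaled arrays, -0.14 with wt5 turned (deposited or centred), -0.19 with the running median removed and reversed to 0.0541 in experiment 2 alone (paired or not), with a leave-out range of -0.45 to -0.13; centred without experiment 1 its call ended as well (adjusted p = 0.0573). Experiment 2 alone has fewer arrays; for the other settings the cause was not tested. The mean r of opposite orientations within experiments was -0.167 with Spearman's correlation. Signal over background was not known, so no limit from dim probes can be given.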

Other observations

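The stress lists and the endothelial list were chosen for description after their values were seen, and so were the test on probes of the same gene and the estimated correlation in fits other than the reported one.

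Heat shock proteins and oxidative stress genes had positive reversing medians in each of the 3 experiments after centring, while as deposited both were negative in experiment 2 (-0.41 and -0.50). The centred heat shock list had medians of 0.19, 0.21 and 0.22 in experiments 1, 2 and 3, and the oxidative stress list 0.22, 0.13 and 0.20. Of the other 11 tested lists the endothelial markers too had a positive median in each experiment after centring, at 0.17, 0.24 and 0.31 (camera adjusted p = 0.408), and a negative one in experiment 2 as deposited (-0.39). The endothelial list was mixed, with 4 of 6 members positive and 2 negative after centring. Its member TEK was negative in each experiment (-1.23, -0.10 and -0.64). Neither stress list passed over the 3 experiments with camera (adjusted p = 0.119 and 0.0950 after centring) or with fry (adjusted p = 0.106 and 0.119). At the preset correlation the oxidative stress list passed in 4 of the fits added after seeing the data, those of centred values with the 4 pairs (adjusted p = 0.0468, or 0.0447 with those of experiment 2 crossed), the 8 arrays with the experiment as a block (0.0395) and the 8 arrays without it (0.0494). With an estimated correlation none of these calls held (adjusted p = 0.830, 0.817, 0.703 and 0.742 in the same order). It did not pass when an experiment was left out (0.157, 0.251 and 0.0737) or when the wt5 array was turned (0.398). HSPB1 itself is a member of the heat shock list.

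Among genes of lists too small to test, the proteasome subunits PSMA4 and PSMA2 had shared values of 0.91 ± 0.76 and 0.58 ± 0.57, while PSMC3 was at -0.04 ± 0.16 and PSMA1 at -0.02 ± 0.15 (SD, n = 3, centred). ZFP36, which binds AU-rich mRNA, had a reversing value of 0.52 ± 0.62 and the related ZFP36L1 0.11 ± 0.85.

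The 3 probes of NRG1, a ligand of ERBB receptors, did not give 1 value. Their reversing means were -0.93 ± 1.72, 0.78 ± 0.04 and 0.26 ± 0.44 (SD, n = 3, centred). In the other genes with several probes the means lay closer together. They were -0.54 and -0.47 for FAS, 0.09 and 0.05 for NOTCH2, and -0.08 and -0.24 for SF1. HGF had -0.75, -0.54 and -0.42, COL4A2 0.07 and 0.45, and CXCL12 -0.40 and 0.03. Over the 7 genes with several probes the mean absolute difference between probes of a gene was 0.467, against 0.346 between random probes (one-sided permutation p = 0.905 for a smaller difference). The probes of NRG1 lay farthest apart and weigh heavily in that mean, which was not computed without them. With 7 genes the test leaves open whether probes of 1 gene measured 1 quantity. Probes for different transcripts could differ as well.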
